A study of Lepeophtheirus salmonis with 21 samples.

How the data were processed

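Copepodids of *Lepeophtheirus salmonis* were studied in 7 groups of 3 pools: a seawater control, an acetone control, and lufenuron at 30, 300, 700, 1000 and 1500 ppb. Groups were taken from the sample labels. Per the labels, lufenuron was diluted in seawater from a stock of 100 mg/L in 50% acetone, and the amount of acetone in the acetone control is not given in the sources used here. Each pool was labelled with Cy5 and hybridised with a Cy3-labelled reference made from all conditions, with no exchange of dyes, on a custom oligonucleotide array with 38132 probe spots among 45220 spots. The 21 arrays lay on 12 slides. Per the file headers, the scanner files hold spot and local background signals in intensity units, read with ImaGene 8.0.1, with 1 file per channel and array. The image sets named in the headers of the Cy3 files fall into 4 scan batches, called A to D here. For 30 ppb replicate 1, 300 ppb replicate 2, 700 ppb replicate 3 and 1500 ppb replicate 1, all in batch A, the Cy5 file named another image set. Their batch is that of the Cy3 channel alone. The deposited value table holds the log2 ratio of Cy5 over Cy3 after the authors' normalization and filtering, for 16259 probes. The exact steps of that normalization are not given in the sources used here. Arrays have no read depth. Signal over local background, with a limit of 2 background SDs, was used in its place, and by it 24237 of 38132 probe spots were above background on all arrays of at least 1 group.

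Before the data were examined, the comparisons, tests, threshold, rule for named probes and most alternatives were fixed, with the scanner files as the planned source. The scanner files were first checked against the value table and against each other. The channels of 1 array share small local flaws in the 5671 unused spots, so files of the same array correlate there. On 17 arrays the Cy5 and Cy3 files matched each other best, and the value table followed their ratio with r of at least 0.976. On 4 arrays they did not match. The Cy5 files of 30 ppb replicate 1 and 300 ppb replicate 2, on 1 slide, each matched the Cy3 file of the other array, so files of 1 channel were exchanged. The value table of each followed its own Cy3 file and the Cy5 file of the other. Its labels were taken as right, which was not tested. The Cy5 files of 1500 ppb replicate 1 and 700 ppb replicate 3, on another slide, matched no array of the series. The value table did not follow the scanner ratio filed for them (r = -0.02 and -0.096). Their values and labels could therefore not be checked against a Cy5 file, and they enter the reported counts at these doses. Because of these 4 arrays the value table was used as the source of every reported count, and the scanner files of the 17 matching arrays became alternatives. This change was made after seeing the data.

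Group means were fitted with limma 3.58.1 in R 4.3.3 to the 21 arrays, with 14 residual and 4.81 prior degrees of freedom, and contrasts were tested with limma's moderated test. A probe was called at a Benjamini-Hochberg adjusted p of 0.05 over the probes tested. The trend is the least-squares slope of the 5 dose means on log10 dose, and limma's moderated F test covered all 7 groups. Each dose against seawater was planned as an alternative choice of control and was made a result of its own after seeing the data, when each pair of doses was also added. The rule for probes to be named, for an array without gene names, allowed at most 2 that rose and 2 that fell. They were the largest changes at 1500 ppb against acetone, among called probes with every array of 1 group above every array of the other. Tests of gene lists were planned but had no members, since 0 of the probe spots carry a gene name or description. Where a spot was below background in one group, a fold was estimated from the Cy5 channel after quantile normalization. Values under the lowest of any probe above background on that array were raised to it. The fold is an estimate and not a strict bound.

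Scores are means per array over a set of probes, signed by direction. The set is the same for all arrays of a setting, but it was chosen anew in each alternative and each omission of an array. Score differences were tested by exact permutation of arrays, over all dose arrays and within scan batches, and relations across 12 or 17 arrays by permutation with 100000 draws, both two-sided, with Benjamini-Hochberg adjustment over the 4 relations tested. The difference profile of acetone minus seawater was correlated across probes with that of a dose minus 30 ppb, which uses other arrays, and the p is from exact permutation over 369600 splits of those arrays. Probes are not independent replicates.

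The pipeline was tested on simulated data of the same size. Values were drawn as independent normal noise with the spread of each probe, without correlation between probes and without array, slide or batch effects. With 200 changed probes, the comparison of 1500 ppb with acetone recovered 7.5% of probes changed 1.5-fold, 49.3% of those changed 2-fold and 93.9% of those changed 4-fold, with 1 unchanged probe called. The trend recovered 71.6%, 97.0% and 98.5% of slopes of 1.5-, 2- and 4-fold per 10-fold dose, with 7 unchanged probes called. With no difference simulated, limma called 0 probes in any of 15 results. This does not cover false calls from structure among the real arrays, which the simulation lacks.

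Alternatives were background correction (normexp offset 50, 10 or none), median centring or scaling in place of loess alone, Cy5 alone, signal median, the filter on dim probes, a 1.5-fold minimum, slide, array position or scan batch in the model, subsets of groups, the choice of control, the form of the trend, array weights, a trended robust prior, and leaving out each array. The restriction of the scanner settings to 17 arrays was chosen after seeing the data. So were the alternatives that use 19 or 21 arrays of scanner files or leave out several arrays. Those that rescale the value table, restrict its probes or block on scan batch were also chosen then.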

Results

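Gene expression was measured in copepodids of the salmon louse *Lepeophtheirus salmonis*, the free-swimming larval stage that infects salmon. The copepodids were exposed to lufenuron, a benzoylurea that blocks chitin formation in arthropods, or to 1 of 2 control treatments. The 5 lufenuron groups received 30 ppb, 300 ppb, 700 ppb, 1000 ppb and 1500 ppb. The acetone control carried the solvent of the lufenuron stock, and the seawater control received neither drug nor solvent. All groups were exposed for 3 h and then held in clean seawater for 21 h. Each group consisted of 3 separate pools of about 500 animals per the labels, so n = 3 pools in every group mean, and SD is the spread between those pools. Each pool was hybridised to 1 of 21 arrays in Cy5 against a common reference pool in Cy3, and all values are log2 ratios of sample over reference. The value table held 16259 probes with no missing values. On the 17 arrays whose scanner files matched, the median Cy5 spot signal ran from 309 to 552 intensity units, and 53.8% to 74.2% of probe spots lay above local background. Of the probes in the value table, 94.9% lay above background on all 17 of these arrays. The number of arrays limits the precision of each comparison. The series title ties lufenuron to moulting, but none of the probes carried a gene name in the sources used here, so transcripts are given by probe ID and genes of chitin synthesis or moulting were not analysed here.

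Pools of the same treatment resembled each other to different degrees. Between pools, the correlation across probes was 0.912 to 0.924 in the acetone control and 0.923 to 0.928 at 1500 ppb. It was 0.779 to 0.796 at 300 ppb and 0.550 to 0.901 at 1000 ppb. The median probe SD between pools was 0.17 at 1500 ppb, 0.18 in the acetone control and 0.29 at 300 ppb, in log2 units. The first principal component held 31.4% of the variance and the second 20.4%. On the second component the 3 acetone arrays (22.0 to 27.0) and the 3 arrays at 1500 ppb (27.1 to 32.9) lay together, while the seawater arrays lay at -8.66 to -1.25. This component also correlated with the log2 Cy5 brightness of the array over 17 arrays (r = 0.518). Brightness as a cause of the grouping was not tested. The first component spread arrays of 1 group apart, most at 1000 ppb, from -25.1 to 72.2.

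**Figure D1:**
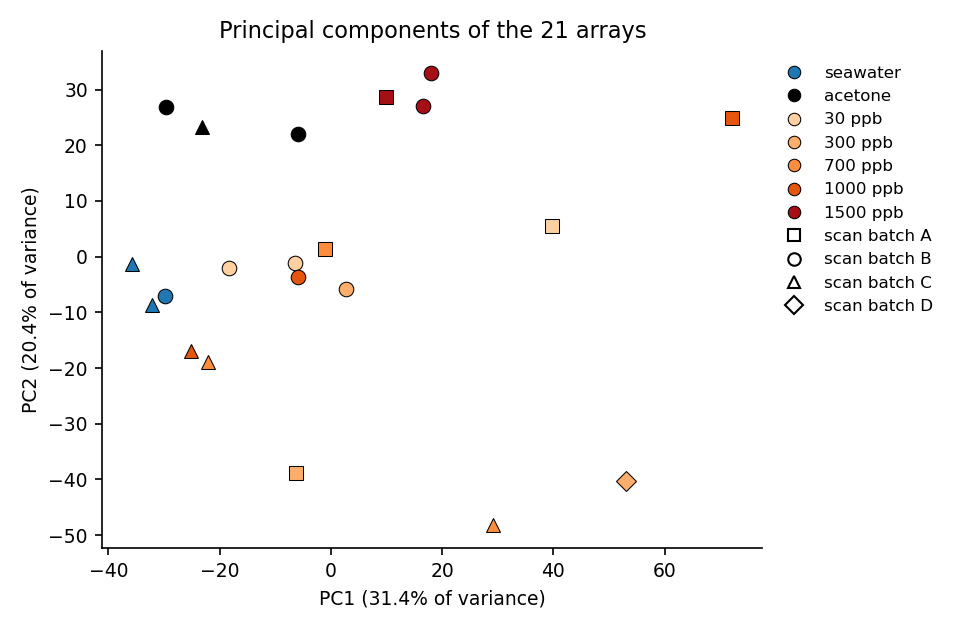
First and second principal components (unitless scores) of the 21 arrays, 1 point per array, coloured by treatment and shaped by scan batch. The acetone and 1500 ppb arrays lie at 22.0 or above on the second component, where 1000 ppb replicate 1 (25.0) is the single array of another group.

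The comparison of the acetone control with seawater addresses the solvent, but it does not isolate it. The acetone arrays lay on slides that held no other group, so the model cannot separate slide from acetone in any contrast with that control. Of 16259 probes 451 differed between these controls, of which 327 were higher and 124 lower in acetone than in seawater. Among these the median absolute change was 0.93 log2 units, and 180 changed at least 2-fold. The largest fitted rise was at CUST_29760_PI416592889, with a mean log2 ratio of 0.61 ± 0.11 (SD, n = 3) in acetone and -3.63 ± 0.27 in seawater (limma adjusted p = 2.33e-08). Its Cy5 spot lay above background on 3 of 3 acetone arrays and on 1 of 3 seawater arrays, so the size of the rise is not firm. The normalized Cy5 signals put the probe at about 8.6-fold higher in acetone, and its rank among the rises is open. With array position as a covariate the count was 145. Without seawater replicate 1, 2 or 3 it was 219, 240 or 274, and without acetone replicate 1, 2 or 3 it was 169, 184 or 177. Within scan batch B (2 acetone arrays, 1 seawater array) limma called 969 probes, and within batch C (1 and 2 arrays) it called 0, with 1094 at an unadjusted p under 0.05; the single array of each is assumed to vary like the other groups.

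Each dose was compared with the acetone control. The amount of acetone in that control is not given in the sources used here, and if the exposures held acetone only from the stock, their share rose with dose from 0.015% to 0.75%. A difference from the acetone control can therefore hold a difference in solvent as well as an effect of lufenuron. It can also hold a difference between slides, since no slide held an acetone array together with another group. Larvae at 30 ppb differed from the acetone control at 506 probes (110 higher, 396 lower), and larvae at 300 ppb at 2696 probes (1408 higher, 1288 lower). At 700 ppb 1146 probes differed (497 higher, 649 lower), at 1000 ppb 623 (218 higher, 405 lower), and at 1500 ppb 127 (38 higher, 89 lower). The order of the doses by count is not firm. With only the compared groups in the fit it was 1536 at 1500 ppb, 1446 at 300 ppb and 131 at 1000 ppb, and without 300 ppb replicate 1 it was 1281 at 700 ppb and 879 at 300 ppb. The median absolute change among these probes was 0.97, 0.84, 0.87, 0.91 and 1.10 log2 units from the lowest to the highest dose. Changes of at least 2-fold were seen at 238, 770, 371, 245 and 78 probes. The split by direction moved with the scaling of the values. It also differed between the value table and the scanner ratios of 17 arrays, where source and set of arrays change together. In the value table without 1500 ppb replicate 1, 2 or 3, 9 of 57, 11 of 62 and 8 of 65 probes were higher at that dose. With the scanner ratios of 17 arrays after loess, an intensity-dependent scaling, 6 of 157, 551 of 1386, 450 of 1295, 102 of 509 and 9 of 67 probes were higher than in acetone from the lowest to the highest dose. With median centring of the same ratios in place of loess, 2 of 244, 162 of 1911, 152 of 3301, 24 of 743 and 3 of 56 were higher. When each array of the value table was centred on its median, 145 of 632 probes at 1000 ppb were higher.

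The counts at 30 to 1000 ppb moved with single arrays of both groups compared. Without acetone replicate 1, 2 or 3, the count was 262, 263 or 221 at 30 ppb, 1670, 980 or 1586 at 300 ppb, 529, 323 or 474 at 700 ppb, and 199, 166 or 377 at 1000 ppb. Among the exposed arrays it was 199 or 261 at 30 ppb without replicate 1 or 2, and 879 or 1695 at 300 ppb without replicate 1 or 2. It was 262 or 1769 at 700 ppb without replicate 1 or 3, and 319 or 238 at 1000 ppb without replicate 2 or 3. Within scan batch B, with 2 acetone arrays, limma called 248 probes at 30 ppb (2 arrays), and 1092 at 300 ppb and 451 at 1000 ppb from 1 array each, which is assumed to vary like the other groups. With batch as a block it called 388, 881, 554 and 582 from 30 to 1000 ppb. Within batch C, with 1 acetone array, limma called 0 at 700 ppb (2 arrays) and at 1000 ppb (1 array), with 2205 and 795 at an unadjusted p under 0.05.

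**Figure D2:**
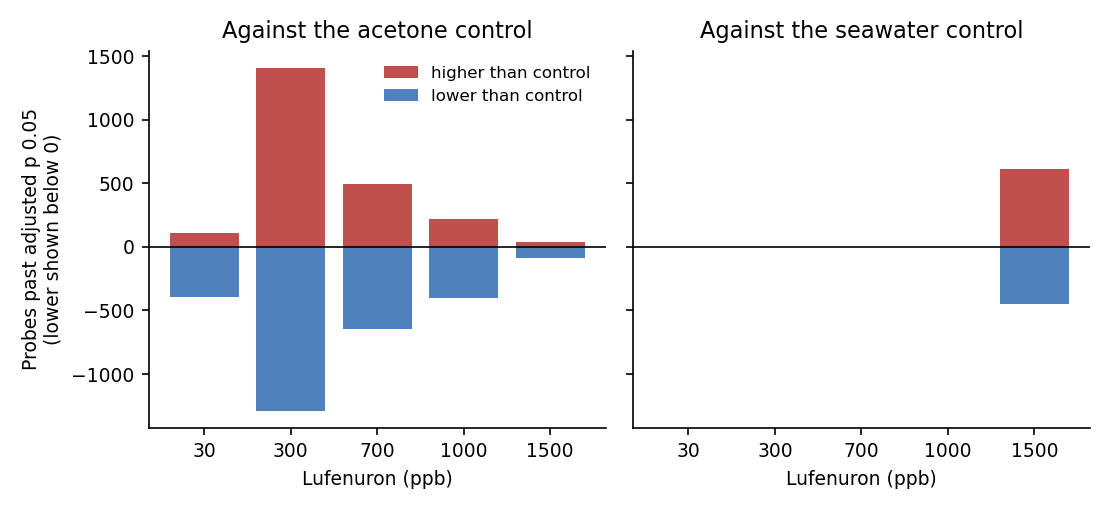
Number of probes past an adjusted p of 0.05 at each lufenuron dose (ppb, 3 arrays per group), against the acetone control (left) and the seawater control (right); bars above 0 count probes higher than the control and bars below 0 count probes lower. Against acetone the counts in this fit are 2696 at 300 ppb and 127 at 1500 ppb, and against seawater they are 1060 at 1500 ppb and at most 1 at any lower dose; other settings change both patterns.

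At 1500 ppb the probe with the largest rise over acetone was CUST_18897_PI416592889. It was 2.93-fold higher (log2 change 1.55 ± 0.28 SE, limma adjusted p = 0.00689), with a mean log2 ratio of 1.84 ± 0.28 (SD, n = 3) against 0.28 ± 0.33 in acetone and -0.33 ± 0.57 in seawater. At the 4 lower doses its means lay between -0.19 and 0.58, and none of these was called against acetone. CUST_1378_PI416592889 was 2.87-fold higher (log2 change 1.52 ± 0.28 SE, limma adjusted p = 0.0085), at 1.16 ± 0.10 against -0.36 ± 0.13 in acetone, -0.23 ± 0.22 in seawater and -0.21 to 0.07 at the lower doses. CUST_29760_PI416592889 was lower by 3.25 log2 units (SE 0.26, limma adjusted p = 2.36e-06). Its Cy5 spot was above background on 0 of 2 matching arrays at 1500 ppb, so the size of the fall is not firm. The normalized Cy5 signals put it at about 6.56-fold lower than in acetone, as an estimate and not a bound. This probe was also low at the 4 other doses, with means of -3.34 to -2.82. CUST_35644_PI416592889 fell by 3.52 log2 units (SE 0.79, limma adjusted p = 0.0392), but it lay above background on only 1 of 3 acetone arrays and 1 of 2 matching arrays at 1500 ppb. Its mean raw Cy5 signal was 167 intensity units in acetone and 6130 at 1500 ppb, the opposite order, so its size and direction are open.

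The count at 1500 ppb against acetone moved with single arrays. Without acetone replicate 1, 2 or 3 it was 77, 63 or 51, and without 1500 ppb replicate 1, 2 or 3 it was 57, 62 or 65. Fitting these 6 arrays alone gave 1536 probes, scan batch as a block gave 73, and batch B alone (2 against 2 arrays) gave 442. The call at CUST_18897_PI416592889 ended without acetone replicate 2 or 3 or without 1500 ppb replicate 3, with changes of 1.41, 1.51 and 1.39. That at CUST_1378_PI416592889 ended without acetone replicate 2 (1.45) or 1500 ppb replicate 3 (1.46), and the largest adjusted p for either was 0.0571 with limma. The call at CUST_35644_PI416592889 ended under 8 of the single-array omissions, with changes of -3.52 without 700 ppb replicate 2, 30 ppb replicate 2 or 1000 ppb replicate 3, -3.26, -3.48 and -3.81 without 1500 ppb replicate 1, 2 and 3, and -3.04 and -3.43 without acetone replicate 2 and 3. That at CUST_29760_PI416592889 held under each omission, at -3.42 to -3.15.

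Comparing each dose with seawater asks what lufenuron and solvent did together. At 1500 ppb 1060 probes differed from seawater, 611 higher and 449 lower. This split by direction is not firm, though each single-array omission kept more probes higher than lower. With the scanner ratios of the matching arrays after loess, 203 were higher and 258 lower. Median centring in place of loess gave 141 and 193, and their Cy5 channel alone gave 280 and 191. With only the compared groups in the fit, 1066 were higher and 1403 lower. With scan batch as a block it was 169 and 154. At 30, 700 and 1000 ppb limma called 0 probes, with 1152, 1878 and 1601 at an unadjusted p under 0.05. At 300 ppb 1 probe was higher, with 3014 at an unadjusted p under 0.05. It was CUST_29916_PI416592889, named here after its values were seen, which was 1.73 log2 units higher (SE 0.26, limma adjusted p = 0.0378), at 0.16 ± 0.46 (SD, n = 3) against -1.57 ± 0.28 in seawater and -0.05 ± 0.46 in acetone. Without seawater replicate 1, 2 or 3 the count at 1500 ppb was 662, 505 or 598, without 1500 ppb replicate 1, 2 or 3 it was 460, 486 or 355, and without 1000 ppb replicate 1 it was 1707. With slide as a fixed block it was 6, 0 of them higher. It was 323 with scan batch as a block and 2353 within batch B (2 arrays against 1). The low counts at the other doses also moved. With array weights, whose estimate stopped before it converged, limma called 76 probes at 30 ppb, 454 at 300 ppb, 0 at 700 ppb (1745 at an unadjusted p under 0.05) and 1775 at 1000 ppb. At 300 ppb the count was 1198 without 300 ppb replicate 3 and 20 without 700 ppb replicate 1. At 300 ppb it was 0 without any other array except acetone replicate 2, 1000 ppb replicates 1 and 2 and 30 ppb replicate 3, each of which left 1. At 1000 ppb it was 4 without seawater replicate 2. Within batch B, which has 1 seawater array, limma called 7 probes at 30 ppb (2 arrays), 10 at 300 ppb (1 array) and 6 at 1000 ppb (1 array), where the single arrays are assumed to vary like the other groups. Within batch C, with 2 seawater arrays, it called 0 at 700 ppb (2 arrays) and 1000 ppb (1 array), with 1539 and 738 at an unadjusted p under 0.05.

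At 1500 ppb 68 probes differed from both controls in the same direction, 25 higher and 43 lower. Both comparisons use the same 1500 ppb arrays, which raises the number in common by an amount not tested. The median log2 ratio of the 25 probes was 0.44 at 1500 ppb, -0.43 in acetone and -0.48 in seawater. That of the 43 probes was -0.88, 0.14 and 0.66. Without 1500 ppb replicate 1, 2 or 3 the number was 24, 25 or 23, and without acetone replicate 1, 2 or 3 it was 37, 28 or 22.

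The mean of the 5 doses differed from acetone at 1500 probes (694 higher, 806 lower) and from seawater at 14 (8 higher, 6 lower). The split moved with scaling, and with source and set of arrays together. With the scanner files of 17 arrays after loess it was 401 higher and 826 lower against acetone, and 3 and 7 against seawater. With median centring in place of loess it was 116 and 1751, and 1 and 23. Leaving out acetone replicate 1, 2 or 3 gave 510, 352 or 470 for the first count. The second was 26 without 300 ppb replicate 3 and 0 to 6 without any array of seawater, acetone, 30 or 1500 ppb, 300 ppb replicate 1 or 2, or 700 ppb replicate 1 or 3. With scan batch as a block limma called 1058 and 0, the latter with 1346 at an unadjusted p under 0.05.

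The trend over dose addresses which transcripts had a slope over the 5 doses. Acetone from the stock would rise with dose as well, so a slope is not one of lufenuron alone, and it does not show a steady change. The limma slope on log10 dose passed at 91 probes, 55 rising and 36 falling, with a median absolute slope of 0.54 log2 units per 10-fold dose. Without 30 ppb replicate 1, 2 or 3 the count was 18, 20 or 34, and without 1500 ppb replicate 1 or 3 it was 47 or 38. With dose in ppb, which gives the highest dose more weight, it was 837. It was 1 with the scanner files of 17 arrays (0 to 5 over their settings), 1 in the value table without the 4 arrays whose Cy5 file did not match, and 0 in limma with slide as a fixed block (297 to 1738 at an unadjusted p under 0.05 over the 4 settings that gave 0). Among the doses themselves, 1500 ppb differed from 30 ppb at 486 probes (299 higher, 187 lower), from 300 ppb at 2115, from 700 ppb at 959 and from 1000 ppb at 363. Between any pair of doses from 30 to 1000 ppb limma called 0 probes. At an unadjusted p under 0.05 there were 2415 between 300 and 30 ppb, 1283 between 700 and 30 ppb, and 1747 between 1000 and 30 ppb. There were 332 between 700 and 300 ppb, 1605 between 1000 and 300 ppb, and 1521 between 1000 and 700 ppb.

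Across all 7 groups limma's F test called 1558 probes. It called 924, 831 or 945 without acetone replicate 1, 2 or 3, and 908, 937 or 861 without 1500 ppb replicate 1, 2 or 3. It called 2476 without 1000 ppb replicate 1 and 2873 without 300 ppb replicate 3. With scan batch as a block it called 688.

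To place each array between the controls, the 451 probes that differed between acetone and seawater were averaged on each array, with the sign of that difference, into an acetone score. The exposed arrays entered the choice of these probes only through the shared spread. This score was -0.62 ± 0.05 (SD, n = 3) in seawater and 0.42 ± 0.03 in acetone. It was -0.48 ± 0.03 at 30 ppb, -0.59 ± 0.03 at 300 ppb, -0.50 ± 0.06 at 700 ppb and -0.42 ± 0.11 at 1000 ppb. At 1500 ppb it was 0.13 ± 0.07, and all 3 arrays there (0.07 to 0.20) lay above all 12 arrays of the lower doses, and so also within scan batches A and B, which hold the 1500 ppb arrays. The difference between 1500 ppb and the lower doses was 0.63 (exact permutation p = 0.0022, two-sided, the smallest that 455 splits can give). Of the 327 probes higher in acetone than in seawater, 124 were also higher at 1500 than at 30 ppb, and of the 124 lower ones 23 were also lower. These comparisons have no array in common, but they share the estimate of each probe's spread, which can raise the overlap by an amount not tested. Over all probes, which are not independent replicates, the differences correlated at r = 0.477, and permuting the arrays gave an exact p of 0.0743 (0.297 after adjustment over 4 doses), so the relation did not pass.

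**Figure D3:**
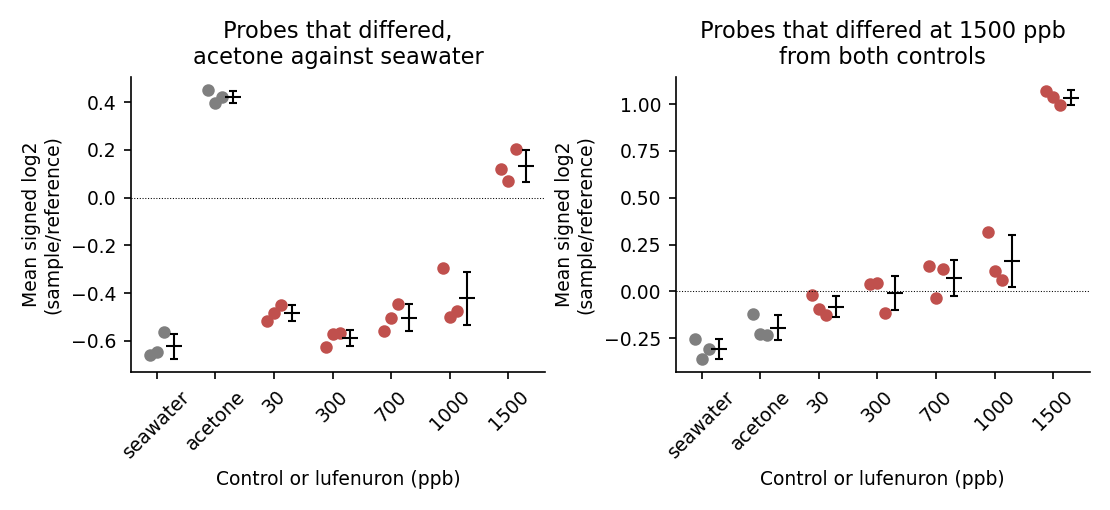
Mean log2(sample/reference) per array, signed by direction of change, over the 451 probes that differed between acetone and seawater (left) and the 68 that differed at 1500 ppb from both controls (right). Points are single arrays and bars the mean ± SD of 3 arrays per group; on the left, 1500 ppb (0.13 ± 0.07) lies toward acetone and the lower doses lie toward seawater, and on the right the height of 1500 ppb follows from how its probes were chosen.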

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

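The tests of the arrangement of the arrays by chance, of scan batch behind the acetone score, of acetone in proportion to the dose, of an acetone level, of Cy5 brightness and of a slide defect, and the comparisons between doses, were chosen after the results were seen. At 1500 ppb 486 probes differed from 30 ppb, 2115 from 300 ppb, 959 from 700 ppb and 363 from 1000 ppb, whereas no pair of the 4 lower doses differed at any probe in limma (332 to 2415 at an unadjusted p under 0.05). These are limma tests of the difference between doses, and they drew attention because the doses share one control.

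The 1500 ppb arrays lay toward the acetone control and the 30 to 1000 ppb arrays toward seawater, in the 451 probes that differed between these controls. For this score a random arrangement of the dose arrays is argued against, by an exact permutation p of 0.011 after adjustment for the choice of 1 of 5 doses, but the split had been seen before it was tested, and over all probes the pattern did not pass, since the profile of 1500 minus 30 ppb correlated with that of acetone minus seawater at r = 0.477 with an exact permutation p of 0.0743 (0.297 after adjustment over 4 doses). Scan batch of the Cy3 channel as the whole cause is argued against for the score. Within batches A and B each 1500 ppb array lay 0.415 or more above every array of a lower dose (exact permutation p = 0.0133, the smallest that the 75 splits keeping to these batches can give). In batch A the Cy5 file of 1500 ppb replicate 1 named another image set, so a batch of the Cy5 channel stays open there. A score that rises linearly with acetone in proportion to the dose is also argued against. The highest of the 3 arrays at 1000 ppb had come 0.309 of the way from 30 to 1500 ppb, where 0.66 would be linear. A response to such acetone that is not linear was not tested. If all acetone came with the stock, its share would be 0.015% at 30 ppb, 0.15% at 300 ppb, 0.35% at 700 ppb, 0.5% at 1000 ppb and 0.75% at 1500 ppb, and a candidate explanation is that it acts only above a level between 1000 and 1500 ppb. All 3 arrays of a dose lay above those of every lower dose only at 1500 ppb. At 1000 ppb, replicate 1 (-0.29) already lay above the highest array of 30 to 700 ppb (-0.44). Drug and solvent rise together, so a step at 1500 ppb cannot be told apart from an effect of lufenuron at that dose. The amount of acetone in the control, on which every count against acetone rests, stays open.

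A set of 31 probes was higher in the acetone control than in seawater and lower at 1500 ppb than in acetone, with a mean log2 ratio of 0.38 ± 0.10 (SD, n = 3) in acetone, -1.37 in seawater and -1.26 at 1500 ppb. For 18 of the 31 a defect of a single slide is argued against. These were called without acetone replicate 3, which lies on another slide than replicates 1 and 2, and on them that array was 1.83 log2 units above the highest array of any other group; for the 10 of them also called without replicates 1 and 2, the gap to the lower of those arrays was 1.85. For the other 13 probes the arrays of both slides entered the choice, so a slide defect stays open. A response to acetone at a level that the exposed groups did not reach, and any other way in which these 3 pools were handled apart from the rest, were not tested and stay open.

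Arrays of 1 group lay far apart on the first principal component, most at 1000 ppb. Scan batch took 0.449 of the variance of this component among arrays (permutation p = 0.015), so scan batch may account for part of the spread, though each batch holds a different mix of groups. Cy5 brightness cannot be told apart from batch: over 17 arrays the component correlated with log2 brightness at r = -0.515 (permutation p = 0.0345, 0.0459 adjusted over 4 relations) and rho = -0.516 (permutation p = 0.036, 0.072 adjusted). The r was -0.439 without the 2 arrays farthest in brightness, -0.363 with batch removed and -0.235 among the 9 arrays of batch B. No biological explanation of the spread within a group was tested.

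Data outside the comparisons also held signal. The Cy5 file under 1500 ppb replicate 1 that matched no array of the series had 40.5% of probes above background, and that under 700 ppb replicate 3 had 52.2%, against 2.5% and 8.01% of unused spots. Their highest correlation with any of the 17 matching arrays was 0.79 and 0.805, and with each other 0.762, while the matching arrays correlated with one another at 0.906 or more.

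Other splits of the same arrays were also fitted with limma. Comparisons of 3 with 3 arrays allow 10 splits, so the share as large as the real one is never under 0.1. For acetone against seawater (451 probes), 30 ppb (506), 300 ppb (2696), 700 ppb (1146) and 1500 ppb (127) against acetone, and 300 ppb (1) and 1500 ppb (1060) against seawater, the real split alone, 1 of 10, gave as many, and the highest other gave 0. At 1000 ppb against acetone it was also 1 of 10, with 623 and a highest other of 3. At 30, 700 and 1000 ppb against seawater the real split gave 0 and all 10 gave as many, with a highest other of 1, 0 and 0. For the mean of the doses against acetone 1 of 100 drawn splits gave as many (1500, highest other 119), and for the F test 1 of 100 (1558, highest other 711). For the mean of the doses against seawater 2 of 100 gave as many (14, highest other 259) and for the trend 2 of 100 (91, highest other 1323), and splits that call several times the real count point to a structure of the samples. For these 4 results the share is under 0.05, not adjusted over results, which argues against a random split of the arrays. For the trend and the mean against seawater it does not exclude one, since a drawn split called 1323 and 259. The drawn splits do not keep to the scan batches, so batch is not excluded by them. With scan batch as a block limma called 1058 probes for the mean against acetone, 688 for the F test, 67 for the trend and 0 for the mean against seawater (1346 at an unadjusted p under 0.05), so the last did not hold with batch in the model.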

How the results depend on the processing

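The scanner settings were planned, but their restriction to 17 arrays was chosen after the data were seen. So were the use of 19 or 21 arrays of scanner files and the block on scan batch. The value table without several arrays, rescaled or with fewer probes was also chosen then. Apart from leaving out 1 array, the alternatives gave 365 counts for the 15 comparisons, of which 186 lay within 1.5 times the reported count and 179 beyond it. Slide as a random block and the trend on dose rank changed none by more than that. No paired analysis was possible because the labels give no replicate number that links a pool of 1 group to a pool of another, and replicate numbers here follow the order of the samples. Tests of gene lists were not run, since no probe has a gene name. Where leaving out an array left 2 pools in a group, limma took the spread from all groups. What limits dim probes is signal over background, as at CUST_35644_PI416592889, whose change was -4.09 to -1.32 with adjusted p from 0.000737 to 0.207 in limma. The change of CUST_29760_PI416592889 was -3.48 to -2.37 in all alternatives, and past the threshold in 41 of 42. That of CUST_1378_PI416592889 was 1.17 to 1.62 and past it in 34 of 44. That of CUST_18897_PI416592889 was 1.32 to 1.74, past it in 35 of 44, but reversed to -0.076 with the scanner files of all 21 arrays as filed, where a Cy5 file of no array of the series stands in for 1 of its 3 pools. The probes of both scores were chosen anew in each alternative, so these compare different sets of probes. The higher acetone score at 1500 ppb than at lower doses held in 37 of 37 alternatives (0.447 to 0.735, exact permutation p 0.0022 to 0.0242, not adjusted for the choice of dose). The correlation over probes of 1500 minus 30 ppb with acetone minus seawater ran from 0.177 to 0.496. Its exact permutation p was 0.0354 to 0.297, not adjusted over the doses. The correlation of the 1500 ppb score with dose ran from -0.002, reversed, without the 3 arrays of lowest weight, to 0.788. At that low end the probes were chosen anew without these arrays. It does not show what leaving them out does to the score of the probes reported. The number of probes changed at 1500 ppb against both controls ran from 10 to 932.

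The counts beyond 1.5 times were as follows, and their cause was not tested except where fewer arrays or probes were fitted. Adding a minimum change of 1.5-fold gave 980 for the mean dose against acetone and 40 for the trend. With slide as a fixed block, which cannot estimate contrasts with acetone, limma gave 0 and 6 (0 higher, 6 lower) for 300 and 1500 ppb against seawater. It gave 0 for the mean dose against seawater and 0 for the trend. Array position as a covariate gave 195, 663, 204 and 60 for 30, 700, 1000 and 1500 ppb against acetone, and 1 and 360 for 1000 and 1500 ppb against seawater. It gave 145 for acetone against seawater, 734 for the mean dose against acetone, 2 for the mean dose against seawater, 28 for the trend and 487 for the F test. Fitting only the groups of each comparison gave 1446, 288, 131 and 1536 for 300, 700, 1000 and 1500 ppb against acetone, and 0 and 2469 for 300 and 1500 ppb against seawater. It gave 4 for the mean dose against seawater and 53 for the trend. Seawater as the control in place of acetone gave 0, 1, 0, 0 and 1060 for 30, 300, 700, 1000 and 1500 ppb, and 14 for the mean dose. Pooling both controls gave 43, 1689, 96, 66 and 514 for these doses, and 497 for the mean dose. A trend on the dose in ppb gave 837 for the trend. Array weights, whose estimate stopped before it converged, gave 2155, 4066, 1893, 5318 and 1764 for 30, 300, 700, 1000 and 1500 ppb against acetone, and 76, 454, 1775 and 4278 for 30, 300, 1000 and 1500 ppb against seawater. They gave 2542 for acetone against seawater, 4274 for the mean dose against acetone, 877 for the mean dose against seawater, 1197 for the trend and 8719 for the F test. An intensity trend and robust variances in eBayes gave 3 and 2 for 300 and 1000 ppb against seawater. They gave 27 for the mean dose against seawater. The scanner files of 17 arrays gave 157, 1386 and 67 for 30, 300 and 1500 ppb against acetone, and 0 and 461 for 300 and 1500 ppb against seawater. They gave 1 for the trend and 600 for the F test. Those files without background correction gave 236, 1764 and 76 for 30, 300 and 1500 ppb against acetone, and 0 and 676 for 300 and 1500 ppb against seawater. They gave 33 for the mean dose against seawater, 1 for the trend and 847 for the F test. Those files with a normexp offset of 10 gave 130, 1258, 373 and 51 for 30, 300, 1000 and 1500 ppb against acetone, and 0 and 396 for 300 and 1500 ppb against seawater. They gave 284 for acetone against seawater, 0 for the mean dose against seawater, 0 for the trend and 449 for the F test. Those files with median centring in place of loess gave 244, 3301 and 56 for 30, 700 and 1500 ppb against acetone, and 0 and 334 for 300 and 1500 ppb against seawater. They gave 24 for the mean dose against seawater and 0 for the trend. Those files scaled between arrays gave 179, 1161 and 76 for 30, 300 and 1500 ppb against acetone, and 0 and 573 for 300 and 1500 ppb against seawater. They gave 0 for the mean dose against seawater, 1 for the trend and 634 for the F test. Their Cy5 channel alone gave 155, 1777 and 68 for 30, 300 and 1500 ppb against acetone, and 0 and 471 for 300 and 1500 ppb against seawater. It gave 0 for the mean dose against seawater, 5 for the trend and 698 for the F test. Their signal median gave 174, 1441 and 61 for 30, 300 and 1500 ppb against acetone, and 0 and 418 for 300 and 1500 ppb against seawater. It gave 1 for the trend and 602 for the F test. Those files without a filter on dim probes gave 132, 847, 712, 264 and 52 for 30, 300, 700, 1000 and 1500 ppb against acetone, and 0 and 265 for 300 and 1500 ppb against seawater. They gave 217 for acetone against seawater, 782 for the mean dose against acetone, 7 for the mean dose against seawater, 1 for the trend and 384 for the F test. Those files with the filter applied to every array gave 151, 1564 and 45 for 30, 300 and 1500 ppb against acetone, and 0 and 434 for 300 and 1500 ppb against seawater. They gave 0 for the mean dose against seawater, 1 for the trend and 736 for the F test. Of the probes called from 30 to 1500 ppb against acetone, 3.8%, 39.8%, 34.7%, 20% and 13.4% were higher with the scanner files of 17 arrays after loess, and 0.8%, 8.5%, 4.6%, 3.2% and 5.4% with median centring in its place.

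Among the other alternatives chosen later, scanner values and changed sets of arrays moved the counts as follows. The scanner files of 19 arrays, with the exchanged pair put back, gave 78 for 1500 ppb against acetone, and 495 for 1500 ppb against seawater. They gave 23 for the mean dose against seawater and 29 for the trend. The scanner files of all 21 arrays as filed gave 29, 125, 65, 19 and 23 for 30, 300, 700, 1000 and 1500 ppb against acetone, and 0 and 58 for 300 and 1500 ppb against seawater. They gave 6 for acetone against seawater, 131 for the mean dose against acetone, 7 for the mean dose against seawater, 0 for the trend and 23 for the F test. The value table without the 4 arrays whose Cy5 file did not match gave 128, 1517 and 42 for 30, 300 and 1500 ppb against acetone, and 0 and 408 for 300 and 1500 ppb against seawater. It gave 0 for the mean dose against seawater, 1 for the trend and 618 for the F test. The value table without 1000 ppb replicate 1, 700 ppb replicate 1 and 300 ppb replicate 3 gave 1022, 5022, 551, 1463 and 336 for 30, 300, 700, 1000 and 1500 ppb against acetone, and 2922 and 2392 for 300 and 1500 ppb against seawater. It gave 1034 for acetone against seawater, 2472 for the mean dose against acetone, 104 for the mean dose against seawater, 287 for the trend and 5020 for the F test. Centring each array on its median gave 0 for 300 ppb against seawater. Scaling between arrays gave 2, 1 and 1 for 300, 700 and 1000 ppb against seawater. It gave 197 for the trend. Keeping only probes above background on the 17 matching arrays gave 1 for the mean dose against seawater. Scan batch as a fixed block gave 881, 554 and 73 for 300, 700 and 1500 ppb against acetone, and 0 and 323 for 300 and 1500 ppb against seawater. It gave 0 for the mean dose against seawater and 688 for the F test.

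Leaving out each array in turn gave 169 to 633 probes for acetone against seawater. Against acetone it gave 199 to 622 at 30 ppb, 879 to 3763 at 300 ppb, 262 to 1769 at 700 ppb, 166 to 844 at 1000 ppb and 51 to 186 at 1500 ppb. Against seawater it gave 0 to 0 at 30 ppb, 0 to 1198 at 300 ppb, 0 to 0 at 700 ppb, 0 to 4 at 1000 ppb and 355 to 1707 at 1500 ppb. For the mean dose it gave 352 to 1941 against acetone and 0 to 26 against seawater, for the trend 18 to 120, and for the F test 831 to 2873. The highest counts against seawater were those without 300 ppb replicate 3 (1198 at 300 ppb) and without 1000 ppb replicate 1 (1707 at 1500 ppb), and the cause was not tested. Limma counts of 0 under these omissions came with 582 to 3136 probes at an unadjusted p under 0.05, and those under the other alternatives with 222 to 4765.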

Other observations

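The test of a graded response below 1500 ppb was chosen after the result was seen. At the 68 probes that differed at 1500 ppb from both controls, values at the lower doses are given here, though limma called 0 probes between any pair of these doses (332 to 2415 at an unadjusted p under 0.05). The 25 higher probes had a median log2 ratio of -0.40 at 30 ppb, -0.24 at 300 ppb, -0.22 at 700 ppb and -0.08 at 1000 ppb, and 0.44 at 1500 ppb. The 43 lower probes had medians of 0.28, 0.29, 0.04 and -0.05 at these lower doses, and -0.88 at 1500 ppb. Averaged with their signs, the score was -0.08 ± 0.06 (SD, n = 3) at 30 ppb, -0.01 ± 0.09 at 300 ppb, 0.07 ± 0.10 at 700 ppb and 0.16 ± 0.14 at 1000 ppb, against -0.31 in seawater and -0.19 in acetone.

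The hypothesis that these transcripts may respond in a graded way below 1500 ppb was tested on the 12 arrays of 30 to 1000 ppb, which did not enter the choice of probes except through the shared spread. The score rose with log10 dose at r = 0.68 (permutation p = 0.0133, 0.0459 adjusted over 4 relations) and rho = 0.756 (permutation p = 0.00708, 0.0283 adjusted). The r was 0.675 without 30 ppb replicates 1 and 2, which lie farthest in dose together with the 30 ppb replicate 3 that was kept. It was 0.701 with scan batch removed. The r moved when single arrays were left out and the probes were chosen anew from the arrays that remained. Without 1000 ppb replicate 1, which also lay farthest out on the first principal component, r was 0.237 (permutation p = 0.47). That choice held 102 probes in place of 68, so the fall cannot be put down to the array alone. The omission was not run with the 68 probes kept. Without 1000 ppb replicate 2, 30 ppb replicate 2 or 30 ppb replicate 3, r was 0.581, 0.598 or 0.609 (permutation p = 0.0569, 0.0548 and 0.0511). It stayed positive and past the threshold in 22 of 37 alternatives, each with its own choice of probes, and the data leave a graded response open. The acetone score of the same 12 arrays gave r = 0.125 (permutation p = 0.7) and rho = 0.324 (permutation p = 0.314) with log10 dose.

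The second principal component correlated with log2 Cy5 brightness over 17 arrays at r = 0.518 (permutation p = 0.0338, 0.0459 adjusted) and rho = 0.478 (permutation p = 0.0554, 0.0739 adjusted). The r was 0.585 without the 2 arrays farthest in brightness and 0.343 among the 9 arrays of batch B.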
